A study of Mus musculus with 6 samples.

How the data were processed

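RNA sequencing was carried out on medullary thymic epithelial cells (mTECs), the thymic stromal cells that present peripheral self-antigens to developing T cells. Per the labels, the cells came from C57BL/6 mice aged 4 weeks and were sorted by flow cytometry. The control mice carried floxed Jmjd3 alleles without Cre (3 mice, Con_253, Con_261 and Con_264 in the labels). The Jmjd3-deficient mice carried the same alleles with Foxn1-cre, which is active in thymic epithelium (3 mice, cKO_262, cKO_263 and cKO_265 in the labels). Jmjd3 is a demethylase of lysine 27 on histone H3 and has the gene symbol Kdm6b. Per the labels' protocols, total RNA was isolated on columns, and the cDNA was amplified with a whole-transcriptome kit made for single cells before Illumina libraries were prepared. Such amplification can favour transcripts by their length and base composition.

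The authors deposited 1 table of FPKM (fragments per kilobase of transcript, scaled to the number of mapped fragments) per library. Per the submitters' processing notes, Bowtie2 2.2.5 and Cufflinks were used with the mouse genome build mm10. The version of Cufflinks, the annotation and any scaling between libraries were not given in the sources used here. A test status column (OK or NOTEST), per the file headers, was identical in all 6 tables. Each table held 25025 rows for 20468 symbols, because genes with several transcript or promoter groups had several rows. Rows of 1 symbol were summed. The 44 rows of 25 symbols that had been turned into calendar dates were left out. They held 0.0930% to 0.138% of the summed FPKM of a library. This left 20443 genes, of which 123 join the symbols of several genes and 144 have rows at more than 1 locus. A gene whose sequence is shared with close relatives, such as kallikreins, defensins, histones, major urinary proteins and ribosomal proteins, has an uncertain value, because the handling of shared reads was not given. Strand was not stated either, so reads of overlapping genes on opposite strands cannot be told apart. Coordinates are those of the tables in mm10. The starts were raised by 1 base, since 9036 of the 18856 symbols found in a RefSeq table began exactly 1 base before the RefSeq start there and 644 began at it.

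The tables hold no counts, so the depth of each library is unknown and counting errors cannot be given. Single-row values above 0 went down to between 2.59e-06 and 4.67e-06 FPKM, which shows fractional assignment of reads, and whole reads were not recovered. Between 854 and 1813 genes per library were listed at 0. A value of 0 may be a failed estimate, so a gene at 0 is described as listed at 0.

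Genes with a mean of at least 0.5 FPKM over the 6 libraries (15720 genes) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, 2-sided). The p-values were adjusted by the Benjamini-Hochberg method, and a gene was called changed at an adjusted p under 0.05. Fold changes are Jmjd3-deficient minus control on the log2(FPKM + 1) scale, with the standard error (SE) of the fit. The added 1 understates the change of low genes. The groups share no replicate numbers, so no pairing was used. Each library is from a separate mouse by its number in the labels.

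Gene lists were written from general knowledge before the data were examined. They comprise 12 lists of tissue-restricted antigen (TRA) genes by organ, their union (All TRA), genes often cited as dependent on the transcriptional regulators Aire or Fezf2, epithelial states, regulatory and metabolic pathways, and markers of other cells a sort could hold. The 39 lists with at least 5 tested members were tested with camera (limma, preset inter-gene correlation of 0.01, 2-sided, Benjamini-Hochberg over the 39 lists). Camera with an estimated correlation and fry were alternatives. As a description of these libraries, each list's median was also placed among those of 10000 random lists of the same size matched on mean expression. The count of members past the threshold is given over all genes and adjusted over the list alone. The numbers of genes at or above 1 FPKM were compared with an exact permutation test (2-sided), which with 3 against 3 libraries cannot give a p below 0.1.

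The genes named were fixed by a rule before the data were examined. It takes Kdm6b, its relative Kdm6a, Aire and Fezf2. It adds the 10 largest rises and the 10 largest falls among changed genes whose groups do not overlap. Where fewer than 10 passed, the list was filled to 10 by the smallest unadjusted p among genes with groups that do not overlap, and these are said not to pass. In each gene list the 2 to 4 members with the smallest unadjusted p are named, apart from some that are not reported here. Predicted genes and clone names are counted but not named.

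Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, quantile normalization, median centring, limma's arrayWeights, leaving out each library in turn, an unadjusted p under 0.05 with a fold of at least 2, and detection at 0.1 or 5 FPKM. After the data had been seen, 3 further steps were added, apart from some comparisons named under the other observations that were also chosen then. The first left out Con_253 and cKO_265 together, the second removed each library's trend with transcript length and GC content (GENCODE M21 transcripts, median per symbol, 99.47% of tested genes with a value), and the third tested 12 further lists and gene families.

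The fit was tested on simulated data for this comparison with 15720 genes, drawn from the real means and the fitted variances. With no gene changed, 0 genes were called. With 200 genes changed, 72.0% of those changed by 1 on the log2 scale and 97.0% of those changed by 2 were called in the right direction, and 3.43% of the 175 calls were unchanged genes. The simulated genes varied independently of each other, which real genes do not. The changed genes were drawn only from those above a set mean expression, so low genes were not covered. The shares also hold for 200 changed genes, so they do not give the power of the real comparison. Tables were read with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.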

Results

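Gene expression was measured by RNA sequencing in mTECs sorted from 3 control mice (Con_253, Con_261 and Con_264) and 3 mice in which Jmjd3 had been targeted in the thymic epithelium (cKO_262, cKO_263 and cKO_265). The title of the series asks about the role of Jmjd3 in the expression of tissue-restricted antigens, genes of peripheral organs that mTECs transcribe and show to thymocytes. The values were FPKM as deposited, and the number of reads behind them is unknown. The summed FPKM was 503908 ± 41114 in the controls and 619347 ± 31808 in the deficient libraries (mean ± SD, n = 3 each). The median gene lay between 3.57 and 3.69 FPKM in the controls and between 3.21 and 3.37 FPKM in the deficient libraries. Correlations of log2 values between libraries, taken across genes, were 0.977 to 0.987 within the controls, 0.958 to 0.977 within the deficient group and 0.950 to 0.980 between groups. cKO_265 stood farthest out on the first principal component (53.02, against -22.7 to 7.42 for the others), which held 42.8% of the variance. The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d reached 7.88, 2.22, 1.28 and 1.18 FPKM in Con_253 and at most 0.058 FPKM in each of the other 5 libraries. These genes came from a sex-linked check that was fixed before the data were examined, and its other gene is not reported here. The labels give no sex, and by these genes Con_253 appeared to be the only library from a male, so the groups did not appear to be matched for sex.

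The targeted gene was read first. Kdm6b (chromosome 11 from 69398518 to 69413675, mm10, protein coding) was at 18.1, 17.1 and 9.998 FPKM in Con_253, Con_261 and Con_264 and at 11.1, 11.6 and 8.67 FPKM in cKO_262, cKO_263 and cKO_265. The mean was 15.1 ± 4.40 FPKM in the controls and 10.5 ± 1.58 FPKM in the deficient group (SD, n = 3 each). The log2 fold change of -0.45 (SE 0.23) did not pass the test (limma, adjusted p = 0.418), and the groups overlapped through Con_264. Without Con_264 the difference was -0.70, and without both Con_253 and cKO_265 it was -0.19. The value covers all exons of the gene together, and the labels do not say which part was deleted, so it does not check the labels. Kdm6a, the X-linked relative of Kdm6b, was at 14.1 ± 5.78 FPKM in the controls and 17.02 ± 4.63 FPKM in the deficient mice (log2 fold change 0.30, SE 0.31, limma adjusted p = 0.703). Its direction turned without Con_253 (-0.03), the library with Y-linked expression.

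Jmjd3-deficient mTECs were then compared with control mTECs. The controls carried no Cre, so a difference cannot be assigned to the loss of Jmjd3 apart from the Cre construct. Among 15720 tested genes 12 changed, 3 of them higher and 9 lower in the deficient cells. The largest rise was that of Slc13a2, a sodium-coupled transporter of citrate and other dicarboxylates in kidney and intestine, which averaged 4.32 ± 0.668 FPKM in the controls and 109.9 ± 18.5 FPKM in the deficient mice (log2 fold change 4.38, SE 0.18, limma adjusted p = 4.57e-05). Abcb11, the bile salt export pump of the liver, rose from 0.544 ± 0.249 to 5.94 ± 1.98 FPKM (log2 fold change 2.14, SE 0.24). Psrc1, a microtubule-associated protein of the mitotic spindle, rose from 19.9 ± 3.10 to 58.0 ± 8.47 FPKM (log2 fold change 1.5, SE 0.17). Defb5, a beta-defensin, was at 6.71, 6.10 and 4.09 FPKM in the controls and was listed at 0 in all 3 deficient libraries (limma adjusted p = 0.00357).

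The other 8 genes that fell included Rgs13, Plcb2 and Avil of the tuft-like list. Rgs13, a regulator of G-protein signalling, fell by 2.04 on the log2 scale (SE 0.18), from 11.9 ± 2.15 to 2.13 ± 0.284 FPKM. Sh2d7, a protein with an SH2 domain, fell by 2.02 (SE 0.23), from 11.8 ± 1.55 to 2.22 ± 0.966 FPKM. Pik3r5, a regulatory subunit of the gamma type of phosphoinositide kinase, fell by 1.91 (SE 0.19), from 57.0 ± 3.17 to 14.7 ± 3.81 FPKM. Plcb2, the phospholipase C of taste transduction, fell by 1.70 (SE 0.21) and the actin-binding advillin gene Avil by 1.58 (SE 0.15). Cyp2g1, a cytochrome of the olfactory mucosa, fell by 1.58 (SE 0.18), from 33.6 ± 5.10 to 10.6 ± 1.81 FPKM. Klk1b16, a glandular kallikrein, fell by 1.48 (SE 0.15), although reads shared with other kallikreins leave its value uncertain. Spag8, a sperm-associated antigen, was at 1.62, 1.43 and 1.58 FPKM in the controls and at 0.07 and 0.15 FPKM in cKO_263 and cKO_265, and it was listed at 0 in cKO_262. Adjusted p-values of these 8 genes (limma) lay between 0.0113 for Rgs13 and 0.0474 for Spag8.

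The changed genes lie on several chromosomes of mm10, and all are annotated as protein coding. Slc13a2 spans chromosome 11 from 78394485 to 78422185, Abcb11 chromosome 2 from 69238282 to 69342616 and Psrc1 chromosome 3 from 108383804 to 108388231. Defb5 spans chromosome 8 from 19247592 to 19250828, Rgs13 chromosome 1 from 144138667 to 144177372 and Sh2d7 chromosome 9 from 54538984 to 54545020. Pik3r5 spans chromosome 11 from 68432125 to 68497846, Plcb2 chromosome 2 from 118707517 to 118728438 and Avil chromosome 10 from 127000709 to 127020994. Cyp2g1 spans chromosome 7 from 26808927 to 26821197, Klk1b16 chromosome 7 from 44136767 to 44141604 and Spag8 chromosome 4 from 43651729 to 43653552.

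Next in order were genes whose groups did not overlap but which did not pass the adjusted threshold (limma). Aif1, a calcium-binding protein of macrophages, averaged 4.29 ± 0.440 FPKM in the controls and 13.7 ± 3.16 FPKM in the deficient mice (adjusted p = 0.0555). The melanocyte antigen gene Mlana was at 0.409 and 0.251 FPKM in Con_253 and Con_264, was listed at 0 in Con_261, and was at 2.34, 2.10 and 3.30 FPKM in the deficient mice (adjusted p = 0.0539). The histone gene Hist2h2bb, which shares sequence with other histone genes, was listed at 0 in Con_253, was at 0.257 and 0.700 FPKM in the other two controls, and was at 5.06, 11.2 and 30.4 FPKM in the deficient mice (adjusted p = 0.0774). Log2 fold changes were 1.07 for Wdfy1, 0.85 for the epoxide hydrolase gene Ephx1, 0.77 for the exocyst gene Exoc4 and 0.90 for Qrich2, with adjusted p from 0.0834 to 0.0986. The tyrosine kinase gene Bmx averaged 23.7 ± 2.51 FPKM in the controls and 7.58 ± 2.33 FPKM in the deficient mice (log2 fold change -1.56, adjusted p = 0.0539).

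**Figure D1:**
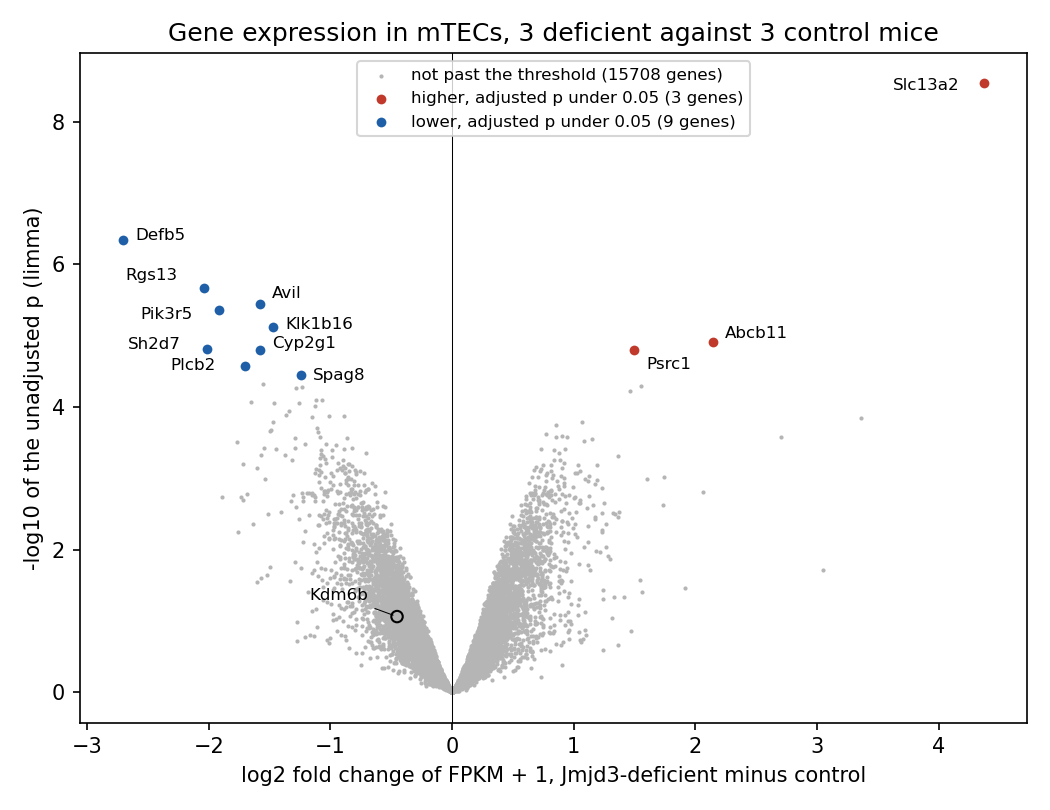
Log2 fold change of FPKM + 1 (x axis, Jmjd3-deficient minus control, 3 mice each) against the -log10 of the unadjusted limma p (y axis), 1 point per tested gene. The 3 genes past the adjusted threshold that were higher are red and the 9 that were lower are blue, Kdm6b is circled, and the position of Defb5 is a fitted value because it was listed at 0 in all 3 deficient libraries.

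At an unadjusted p under 0.05, 1071 genes were higher and 1230 lower, where 786 in all would be reached by chance. The 3 libraries of each group did not overlap for 1507 genes with higher and 1868 with lower values in the deficient mice, 21.5% of tested genes, where chance gives 10%. The number of changed genes was 2 when any 1 control library (Con_253, Con_261 or Con_264) was left out, 23 without cKO_262 and 19 without cKO_265, and 8 without both Con_253 and cKO_265. Slc13a2 passed the threshold in all 14 refits and Defb5 in all 13 in which it was tested.

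The list with the median farthest from 0 was that of tuft-like mTECs, thymic cells that share the chemosensory program of intestinal tuft cells. All 21 tested genes of this list had lower values in the deficient mice, with a median log2 fold change of -1.08. Of these, 3 passed the threshold over all genes (Rgs13, Avil and Plcb2), and 18 passed adjusted over the list alone. The lower members included the taste G-protein gene Gnat3 (9.05 ± 2.72 against 2.15 ± 0.551 FPKM, adjusted p = 0.0623 over all genes), Avil (40.8 ± 5.21 against 12.9 ± 1.08 FPKM) and Plcb2 (11.03 ± 2.41 against 2.68 ± 0.561 FPKM). The list fell as a group (camera adjusted p = 3.94e-21), but did not pass with an estimated correlation (camera unadjusted p = 0.0103, adjusted p = 0.403). Fry, which asks whether the genes of the list move one way on balance, gave an adjusted p of 0.0229. Relative to the mean of the controls, the list's median was between -0.124 and 0.182 in the controls, and it was -1.13, -1.03 and -1.29 in cKO_262, cKO_263 and cKO_265. The thymocyte list was also lower in the deficient libraries, with a median of -0.31 and its T-cell genes Cd8b1 and Cd3e at -1.07 and -1.06.

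**Figure D2:**
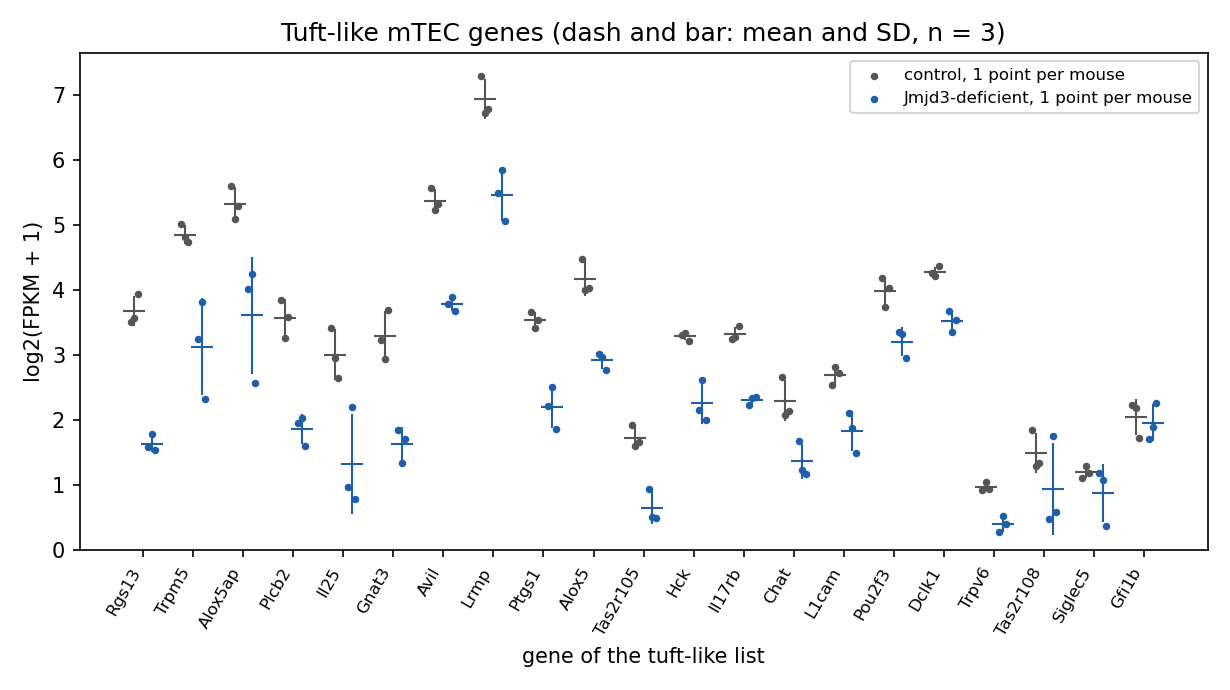
Expression of the 21 tested genes of the tuft-like list as log2(FPKM + 1), 1 point per mouse, with dashes for the mean and bars for the SD of 3 mice per group, ordered by fold change. Every gene had a lower mean in the Jmjd3-deficient mice, and for 18 of them the difference passed adjusted over the list alone.

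Tissue-restricted genes were the subject of the series. The tissue lists hold only a part of such genes, and the counts here cover the listed genes only. The changed genes Slc13a2 and Abcb11, which rose, and Cyp2g1 and Klk1b16, which fell, were described above by organ but are in no tissue list. Of the 237 tested genes of the union of the 12 tissue lists, 0 passed the threshold over all genes (limma), while 19 higher and 27 lower genes had an unadjusted p under 0.05. Adjusted over the list alone, 1 gene was higher and 9 were lower. Of the list's members 94 had higher and 143 lower values in the deficient mice, and the median was -0.08 as deposited and 0.00 under quantile normalization and median centring. Among all 15720 tested genes, 1071 higher and 1230 lower genes had a limma unadjusted p under 0.05. Camera, which compares the list with the other genes, gave an adjusted p of 0.621, and of 0.852 with an estimated correlation. Fry, which tests the list for a change in one direction, gave an adjusted p of 0.428. Both look for a shift in one direction, in which rises and falls cancel, so a change in both directions at once was not tested. The genes of the list with the smallest p were Cyp2f2, Fgg, Muc5ac and Umod. The airway cytochrome gene Cyp2f2 averaged 30.3 ± 3.18 FPKM in the controls and 16.1 ± 2.92 FPKM in the deficient mice (adjusted p = 0.118). The fibrinogen gene Fgg averaged 29.2 ± 11.7 and 100.5 ± 40.7 FPKM, the gastric mucin gene Muc5ac 3.67 ± 0.801 and 1.26 ± 0.404 FPKM, and the uromodulin gene Umod 5.86 ± 0.859 and 2.84 ± 0.166 FPKM. Without cKO_262 the direction of the list's test turned, with a median of -0.01.

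Of the 12 tissue lists 0 passed camera, with adjusted p from 0.163 for the pancreas list, the 1 list with an unadjusted p under 0.05, to 0.964 for the liver list, and 0 passed with an estimated correlation or with fry. Without cKO_263 the pancreas list passed (median -0.32, adjusted p = 0.0171). Medians were -0.17 for pancreas, -0.16 for lung and airway, -0.14 for brain and neuron, -0.11 for liver, -0.09 for stomach and intestine, -0.08 for testis and germline, and -0.07 for thyroid, adrenal, pituitary and bone. They were -0.05 for kidney and urogenital, -0.04 for skin and hair, -0.02 for retina and lens, 0.01 for muscle and heart, and 0.03 for salivary, mammary and lacrimal gland. With 1 library left out, they ranged from -0.32 to -0.11 for pancreas, -0.23 to -0.04 for lung and airway, -0.14 to -0.08 for brain and neuron, -0.18 to -0.02 for liver and -0.16 to -0.04 for testis and germline, and those of the other 7 lists turned. Medians were 0.08 without Con_261 and 0.01 without cKO_262 for stomach and intestine, 0.01 without Con_261 for kidney, 0.10 without cKO_262 for the endocrine and bone list, and 0.0048 without cKO_262 for skin. They were 0.04 without Con_264 or cKO_262 for retina and lens, -0.10 without Con_264 and -0.09 without cKO_263 for muscle and heart, and -0.15 without cKO_265 for the gland list. The liver list held its largest differences in 1 complex, with the fibrinogen genes Fgg and Fga at log2 fold changes of 1.74 and 0.77, against a negative median. In the pancreas list the lectin gene Reg3a was at -1.33 and the colipase gene Clps at -1.12. In the stomach and intestine list Muc5ac and the proton pump gene Atp4a were at -1.05 each, and in the lung and airway list Cyp2f2 was at -0.88 and the secretoglobin gene Scgb3a1 at -0.89.

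Other tissue lists likewise held both higher and lower members, but in some of them the genes named here went the same way. In the muscle and heart list the slow troponin gene Tnni1 was at 0.64 and the myogenic factor gene Myog at -1.40. In the brain list Pcp4 was at 1.36 and the tachykinin gene Tac1 at 0.80, and in the retina and lens list the photoreceptor gene Guca1a was at -1.19 and the lens gene Mip at -0.56. In the testis and germline list the zona pellucida gene Zp2 was at -1.15 and Tex14 at 0.58, and in the skin list the keratin gene Krt10 was at -1.13 and Krtdap at 0.64. In the kidney list Umod was at -0.83 and the glucose transporter gene Slc5a2 at -0.59. In the gland list Dcpp2 was at -0.68 and Bpifa2 at -0.53, and in the endocrine and bone list the glycoprotein hormone gene Cga was at 0.69 and the steroid enzyme gene Cyp17a1 at -0.86. Each of these genes had an adjusted p over all genes between 0.122 and 0.369 (limma). The medians of the kidney, retina and skin lists were positive under quantile normalization (0.02, 0.10 and 0.02) and under median centring, and that of the endocrine and bone list under median centring (0.01). Among genes of at least 5 FPKM the medians were 0.23 for the endocrine and bone list, 0.045 for brain and -0.14 for muscle and heart.

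**Figure D3:**
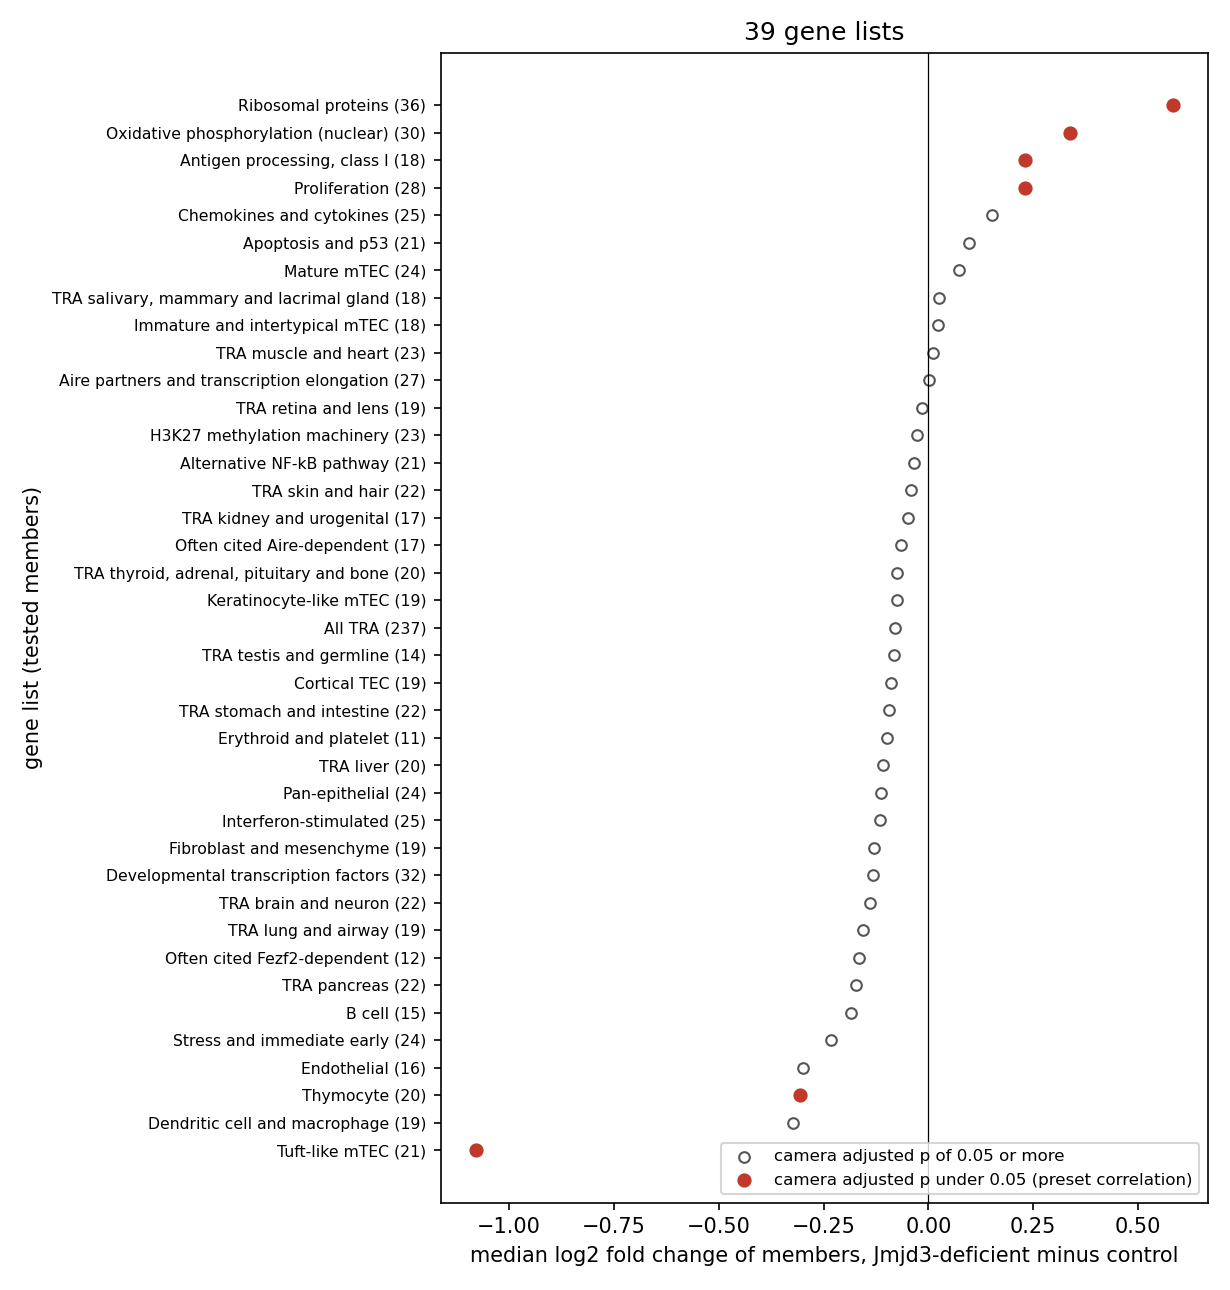
Median log2 fold change of the tested members (x axis, Jmjd3-deficient minus control) of each of the 39 gene lists (y axis, number of tested members in brackets). Filled red points are the 6 lists past camera's adjusted threshold with a preset correlation, of which 0 passed with an estimated correlation.

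Aire, which drives the expression of many tissue-restricted genes, averaged 325.7 ± 86.5 FPKM in the controls and 425.8 ± 97.0 FPKM in the deficient mice (log2 fold change 0.40, SE 0.25, limma adjusted p = 0.5004). Fezf2, a second such regulator, averaged 219.7 ± 28.7 and 220.2 ± 24.0 FPKM (log2 fold change 0.01, SE 0.16, limma adjusted p = 0.990), with a sign that turned in 5 refits. The 17 tested genes often cited as Aire-dependent had a median of -0.07 (camera adjusted p = 0.778), led by Pcp4 at 1.36 and the transglutaminase gene Tgm3 at -0.89. The 12 often cited as Fezf2-dependent had a median of -0.17 (camera adjusted p = 0.430), led by Krt10 at -1.13 and Resp18 at -0.29. The median of the Aire-dependent genes turned under median centring (0.02), among genes of at least 5 FPKM (0.07), without Con_253 (0.02) and without cKO_262 (0.01), and was -0.21 without cKO_265. That of the Fezf2-dependent genes was -0.07 without cKO_262 and -0.09 without Con_261. The partners of Aire and of transcription elongation had a median of 0.00 (camera adjusted p = 0.856), with Jmjd6 at -0.56 and Crebbp at -0.47, and of -0.04 without Con_261 or cKO_263.

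Markers of the maturation state of mTECs did not pass as groups. The mature mTEC list had a median of 0.07 (camera adjusted p = 0.296), which was -0.14 under quantile normalization, and adjusted over the list alone 3 of its 24 genes were higher and 1 was lower. Within it Cd24a averaged 215.8 ± 7.31 FPKM in the controls and 146.7 ± 2.2 FPKM in the deficient mice, while the receptor gene Tnfrsf4 averaged 9.47 ± 0.596 and 19.3 ± 7.01 FPKM. The immature and intertypical list had a median of 0.02 and a mean of -0.21 (camera adjusted p = 0.624), and it passed under quantile normalization with a median of -0.26 (adjusted p = 0.00265). Within it the apolipoprotein gene Apoe averaged 307.6 ± 57.6 and 143.6 ± 20.5 FPKM, Igfbp5 75.6 ± 6.78 and 26.3 ± 13.3 FPKM, and the basal epithelial factor gene Trp63 19.1 ± 2.92 and 10.6 ± 0.618 FPKM, with limma adjusted p of 0.0986, 0.118 and 0.118. Medians and camera adjusted p-values were -0.08 and 0.714 for the keratinocyte-like list (Krt77 at -1.29, Krt10 at -1.13), -0.09 and 0.624 for the cortical epithelial list (Pax1 at -1.02, Isl1 at -0.70), and -0.11 and 0.525 for the pan-epithelial list (Trp63 at -0.79, Elf3 at -0.61). The pan-epithelial list passed under quantile normalization (median -0.30, adjusted p = 1.88e-06), but its median was 0.03 without Con_261, 0.02 without cKO_265 and 0.003 without both Con_253 and cKO_265. The cortical median turned to 0.02 under quantile normalization and was -0.21 without Con_261, and the keratinocyte-like median turned under median centring (0.01) and without Con_264 (0.001) or cKO_262 (0.02). Negative medians were found for the immature list without Con_264 (-0.03), cKO_262 (-0.08), cKO_263 (-0.001) or cKO_265 (-0.05) and for the mature list without Con_264 (-0.0026).

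Of the lists past camera with the preset correlation, 4 were higher, and they stood apart to different degrees from random lists of the same mean expression. Among 10000 such lists the median of the ribosomal list lay at percentile 100, proliferation at 99.97, oxidative phosphorylation at 95.8 and class I antigen processing at 54.2. All 36 tested ribosomal protein genes had higher values in the deficient mice (median 0.58, camera adjusted p = 3.94e-21, 0.542 with an estimated correlation). Adjusted over the list alone, 27 passed, and over all genes 0 did in limma, where 29 had an unadjusted p under 0.05. Rps15 averaged 3502 ± 699 FPKM in the controls and 7576 ± 1484 FPKM in the deficient mice. Reads shared with ribosomal pseudogenes leave these values uncertain. Under quantile normalization the median was 0.18. The nuclear genes of oxidative phosphorylation had a median of 0.34, 23 of 30 being higher (camera adjusted p = 5.10e-06, 0.561 with an estimated correlation). Among them Ndufa2 averaged 178.3 ± 34.6 and 377.2 ± 61.0 FPKM, and Cox7a2 97.7 ± 5.41 and 163.5 ± 21.8 FPKM. This call was lost under quantile normalization (median 0.09, adjusted p = 0.319), and without Con_264 the median was 0.18.

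Of 28 proliferation genes, 23 had higher values (median 0.23, camera adjusted p = 4.18e-05, 0.561 with an estimated correlation), and 0 passed adjusted over the list alone in limma, where 9 had an unadjusted p under 0.05. The mitotic kinesin gene Kif20a averaged 22.8 ± 1.86 and 35.5 ± 5.28 FPKM, and the spindle factor gene Tpx2 18.7 ± 1.68 and 26.95 ± 0.951 FPKM. Without Con_264 the median was 0.35. Of 18 genes of class I antigen processing, 16 had higher values (median 0.23, camera adjusted p = 6.78e-04, 0.542 with an estimated correlation), but the median was that of ordinary genes of the same expression (percentile 54.2). The proteasome genes Psme2 and Psmb9 averaged 284.9 ± 35.7 and 133.9 ± 18.9 FPKM in the controls against 528.9 ± 159.9 and 188.8 ± 15.6 FPKM in the deficient mice. The direction of this list turned under quantile normalization (median -0.03, adjusted p = 0.941).

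Markers of other cells that a sort could carry along were measured beside the mTEC genes. Levels within 1 list differed widely, so they do not measure how many such cells were present. In the controls the lysozyme gene Lyz2 was at 344.6 ± 19.1 FPKM and the macrophage gene Mpeg1 at 1.36 ± 0.464 FPKM, and Spib, which mTECs also express, was at 157.5 ± 23.3 FPKM and the B-cell receptor gene Cd79a at 2.61 ± 0.753 FPKM, all named after their values had been seen. Percentiles among random lists of the same expression were 0.19 for thymocytes, 0.01 for dendritic cells and macrophages and 0.9 for endothelium, and of the other lists that did not pass camera, stress genes lay at 0 and pan-epithelial genes at 0.08. The thymocyte list fell (median -0.31, 17 of 20 lower, camera adjusted p = 0.00604, 0.561 with an estimated correlation). Within it the T-cell receptor subunit gene Cd3e averaged 2.22 ± 0.391 and 0.609 ± 0.631 FPKM. The thymocyte call was lost without Con_253 (median -0.25, adjusted p = 0.152), without both Con_253 and cKO_265 (adjusted p = 0.148), with arrayWeights (adjusted p = 0.162) and among genes of at least 5 FPKM (adjusted p = 0.0967). Medians and camera adjusted p-values were -0.19 and 0.681 for B cells (Vpreb3 at -0.71, Cr2 at 0.48), -0.32 and 0.411 for dendritic cells and macrophages (Aif1 at 1.46, Bst2 at 0.42), and -0.30 and 0.163 for endothelium (Sox18 at -1.26, Pecam1 at -0.56). The endothelial list passed fry (adjusted p = 0.0397). They were -0.13 and 0.432 for fibroblasts and mesenchyme (Col6a2 at -1.23, Twist1 at -1.02) and -0.10 and 0.778 for erythroid cells and platelets (Beta-s at 1.19, Ppbp at -0.63), the erythroid median being 0.04 under quantile normalization. The B-cell median was 0.20 among genes of at least 5 FPKM, -0.09 without cKO_262 and -0.10 without cKO_265, the fibroblast median -0.01 without Con_264, the erythroid median -0.01 without cKO_262 and the endothelial median -0.14 without cKO_265.

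Regulatory lists did not pass camera. The H3K27 methylation machinery had a median of -0.03 (adjusted p = 0.856), with the Polycomb gene Cbx2 at -0.48. Developmental transcription factors that are classical Polycomb targets had a median of -0.13 (adjusted p = 0.659), with Isl1 at -0.70 and Tbx5 at 0.40, and adjusted over the list alone 0 of 32 passed in limma, where 1 higher and 1 lower gene had an unadjusted p under 0.05. Under quantile normalization the medians of these lists were 0.01 and 0.02, the first was 0.07 without cKO_262, and the second was -0.03 without Con_261. The alternative NF-kB pathway had a median of -0.04 (adjusted p = 0.714), with Nfkbie at 0.60 and Cd40 at 0.43, and turned to 0.05 under median centring, 0.07 without Con_253 and 0.01 without cKO_265, while chemokines and cytokines had a median of 0.15 (adjusted p = 0.0840), with Il15 at 0.78 and Il1rn at 0.62. Stress and immediate early genes had a median of -0.23 (adjusted p = 0.341), with Atf3 at -0.53 and Ier3 at -0.57, and genes of apoptosis and p53 a median of 0.10 (adjusted p = 0.153), with Ccng1 at 0.93 and Cdkn1a at 0.71. The chemokine list passed without cKO_262 (median 0.27, adjusted p = 0.00810), without cKO_263 (median 0.26, adjusted p = 0.0222) and with no filter, but its median was 0.01 both without cKO_265 (adjusted p = 0.664) and with arrayWeights (adjusted p = 0.441), and 0.07 without Con_253. The stress list passed without Con_264 (median -0.30, adjusted p = 0.00841) and under quantile normalization, but had a median of -0.06 without both Con_253 and cKO_265 (adjusted p = 0.985). The p53 list passed with the length and GC trends removed (median 0.15, adjusted p = 0.0230) and the interferon list under quantile normalization (median -0.16, adjusted p = 0.0319). Interferon-stimulated genes had a median of -0.12 (adjusted p = 0.624) and held the antiviral gene Mx2, which was at 0.018 FPKM or less in each control and at 7.19, 1.86 and 11.2 FPKM in cKO_262, cKO_263 and cKO_265 (limma adjusted p = 0.0986). In the interferon list Irf7 averaged 69.8 ± 3.09 and 35.7 ± 10.8 FPKM. The signs of the median and of camera's direction differed for the alternative NF-kB, erythroid, liver, immature mTEC and Aire partner lists, and the mean of the salivary gland list (-0.01) was negative against its median.

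The breadth of expression was compared last. At 1 FPKM or more, 14024, 14178 and 14205 genes were detected in Con_253, Con_261 and Con_264, and 13753, 13801 and 13668 in cKO_262, cKO_263 and cKO_265. The means differed by -395 genes (exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). Of 290 measured tissue-restricted genes, 203.3 ± 3.51 were detected per control library and 196.7 ± 4.51 per deficient library (SD, n = 3 each, exact permutation p = 0.2). At 0.1 FPKM they were 278.7 ± 4.04 and 272.3 ± 1.15, and at 5 FPKM 108 ± 2.65 and 100 ± 4.36 (exact permutation p = 0.1 each). These genes held 0.946% ± 0.0475 of the summed FPKM in the controls and 0.786% ± 0.0867 in the deficient libraries (exact permutation p = 0.1). Their own sum was 4759 ± 323 FPKM in the controls and 4888 ± 770 FPKM in the deficient libraries (exact permutation p = 0.8), so the lower share went with the higher total. The 10 most abundant genes held 10.7% ± 0.664 and 14.9% ± 1.74 (exact permutation p = 0.1).

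The gene with the largest rise, Slc13a2, lies beside Foxn1, the gene after which the Cre construct is named. Foxn1 spans chromosome 11 from 78358288 to 78386558, and both genes are on the minus strand, so that Slc13a2 lies 7.93 kb beyond the start of the Foxn1 transcript. Foxn1, the master regulator of thymic epithelium, was named after its values had been seen and averaged 34.8 ± 4.29 FPKM in the controls and 29.2 ± 2.71 FPKM in the deficient mice (log2 fold change -0.24, SE 0.15, limma adjusted p = 0.498). The other 48 tested genes within 1000 kb had a median log2 fold change of -0.12, with a range from -0.57 to 1.16. The lowest limma adjusted p among them was 0.138.

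**Figure D4:**
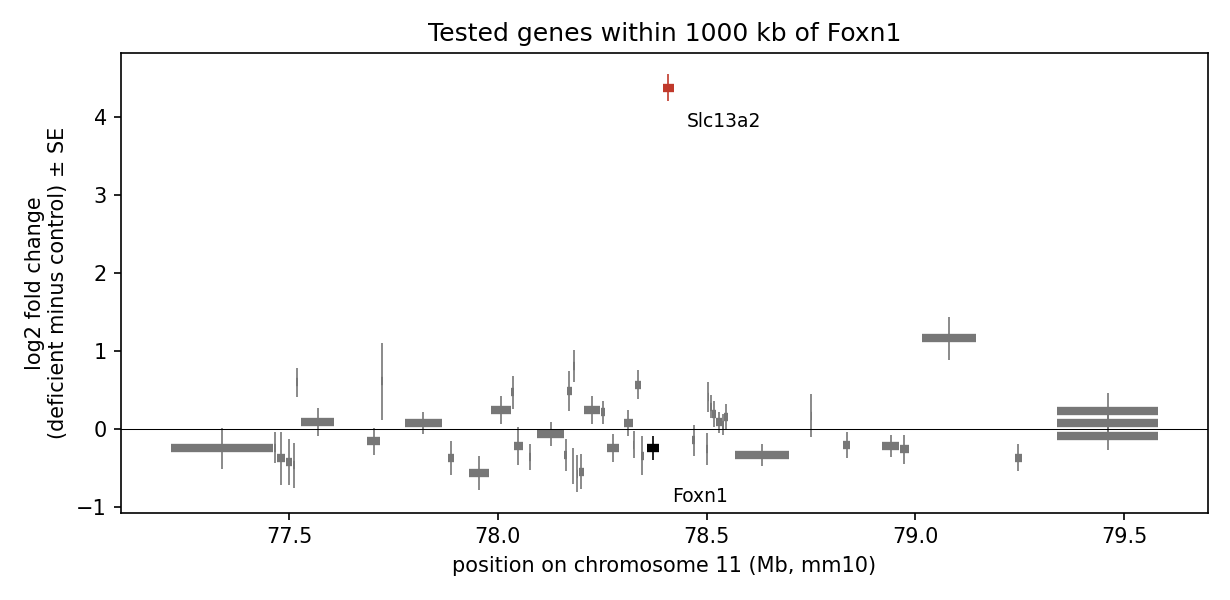
Log2 fold change ± SE (y axis, Jmjd3-deficient minus control) of the tested genes within 1000 kb of Foxn1, drawn at their positions on chromosome 11 of mm10 (x axis, Mb). Slc13a2 (red, 4.38) is past the adjusted threshold, Foxn1 is black (-0.24), and the other 48 genes are grey.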

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

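Leaving out Con_253 together with cKO_265, and removing the trends with transcript length and GC content, were chosen after seeing the data, and the other settings before. Depth is unknown, so it limits every value by an amount that cannot be given. The 12 changed genes became 3025 with arrayWeights, which gave Con_261 a weight of 8.72 and cKO_265 one of 0.263, and 58 with the length and GC trends removed. They became 195 at an unadjusted p under 0.05 with a fold of at least 2, and between 2 and 23 when 1 library was left out. The 12 genes were also among the calls in both of the first settings. Counts of 8 to 18 were found under the other 6 settings, and the 12 genes kept their direction in every refit that tested them. The 6 lists past camera became 0 with an estimated correlation. That setting also lost the neuroendocrine-like list described below, whose estimated correlation of -0.024 was under the preset 0.01. Its camera adjusted p went from 8.88e-04 to 0.0611, so such a loss does not measure correlation alone. With fry 2 lists passed, 1 of the 6 (tuft-like) and the endothelial list. Lists past camera were between 5 and 8 otherwise, with 2 up and 6 down under quantile normalization against 4 up and 2 down as deposited. The tuft-like median of -1.08 was not past the threshold with an estimated correlation (adjusted p = 0.403) and was past it in the other 15 settings, with medians from -1.48 to -0.97. The median of the tissue-restricted genes ranged from -0.122 to -0.0146 when 1 library was left out, the test's direction turning at the latter without cKO_262. It was 0.0042 under quantile normalization and 0.0016 under median centring, and camera's adjusted p stayed between 0.281 and 0.812 over its refits. Kdm6b was past the threshold only with arrayWeights (-0.53, adjusted p = 0.0392, against 0.355 to 0.794 otherwise). The class I antigen processing list turned under quantile normalization (-0.0310). Kdm6a turned without both Con_253 and cKO_265 (-0.21) and ranged from -0.0299 to 0.562 when 1 library was left out. Fezf2 turned under quantile normalization (-0.27) and arrayWeights (-0.0449) and ranged from -0.11 to 0.10 when 1 library was left out. The difference in detected genes was -701 at 0.1 FPKM and -285 at 5 FPKM, both with an exact permutation p of 0.1. The cause of these changes was not tested, and where 1 or 2 libraries were left out there were also fewer libraries to test with. No paired analysis was possible because the groups share no replicate numbers.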

Other observations

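The lists of this part, the removal of length and GC trends, the comparison with blood cell markers, the share of lower tuft-like genes and both comparisons around Foxn1 were chosen after the results had been seen. Further mTEC subtypes and gene families were tested in 12 lists, with camera's adjusted p over these 12. Because they were chosen so late and some hold genes already called changed, their p-values describe these libraries and are no separate support. A second set of 27 tuft-cell genes, which includes the changed genes Pik3r5 and Sh2d7, had lower values for 25 (median -0.61, adjusted p = 4.01e-10, 0.0611 with an estimated correlation). Ciliated-like genes were lower for 16 of 17 (median -0.31, adjusted p = 1.65e-05, 0.0955 with an estimated correlation), among them Spag8, Nme9 at -1.55 and Stk33 at -1.07. Neuroendocrine-like genes were lower for 15 of 19 (median -0.38, adjusted p = 8.88e-04, 0.0611 with an estimated correlation), led by Scg2 at -0.85 and Celf3 at -0.98. Goblet and secretory genes were lower for 14 of 18 (median -0.23, adjusted p = 0.00263, 0.0611 with an estimated correlation), led by the chloride channel regulator gene Clca3 at -1.24 and Muc5ac at -1.05. The kallikrein 1 family, whose members share reads, was lower for 13 of 14 (median -0.69, adjusted p = 1.58e-08, 0.0611 with an estimated correlation), led by Klk1b16 and by Klk1 at -1.07.

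Mitochondrial ribosomal protein genes were higher for 67 of 76 (median 0.28, adjusted p = 6.37e-12, 0.0611 with an estimated correlation), led by Mrpl40 at 1.03 and Mrpl55 at 0.68. The other 6 lists did not pass. Their medians were -0.27 for ionocyte-like genes (adjusted p = 0.117), 0.07 for microfold-like genes (0.0666, with Aif1 at 1.46 and Icam4 at 1.15), -0.14 for muscle-like genes (0.443), -0.10 for enterocyte and hepatocyte-like genes (0.561), 0.12 for beta-defensins (0.650) and 0.08 for histone genes (0.587). Of the 16 microfold-like genes 9 were higher and 7 lower, the lower ones including Gp2 at -0.99. With the length and GC trends removed, 58 genes passed, 18 higher and 40 lower, including the 12 changed genes, 8 genes of the tuft-like list, 4 of the second tuft set and 2 kallikreins. Per library, the Spearman correlation across genes between GC content and the deviation from the control mean was taken. It was 0.485 in Con_253, 0.335 in Con_261, -0.651 in Con_264, 0.239 in cKO_262, 0.04 in cKO_263 and -0.340 in cKO_265. Genes are not independent replicates, and these values describe single libraries.

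For the lower tuft-like genes, trends with length and GC content are argued against, since the median was -1.10 with them removed. Fewer blood cells carried along in the sort were examined through 54 markers of thymocytes, B cells, dendritic cells and macrophages. Their median was -0.27 (95% bootstrap interval over genes -0.40 to -0.18) against -1.08. The lists taken apart had intervals from -0.62 to -0.19 for thymocytes, -0.42 to 0.105 for B cells and -0.435 to -0.038 for dendritic cells and macrophages. The 25 markers with a mean from 1 FPKM to the 6.52 FPKM of the median tuft-like gene had an interval from -0.42 to -0.16. Of the 54 markers 2, Cd8b1 at -1.07 and Cd3e at -1.06, were within 1 SE of the tuft-like median. The markers as a set thus fell less than the tuft-like genes. However, mTECs also express some of them, such as Spib, and the intervals are over genes and not mice. Fewer blood cells are therefore not excluded as a source. That 100% of the 21 tested genes had lower values is the observation itself and no test of its source. A smaller share of tuft-like cells among the sorted mTECs and lower expression per cell both stay open. Under either, the loss of Jmjd3 and the Cre construct are not separated by the design. Only 10 splits of the 6 libraries into 3 and 3 exist, too few to judge chance. The real median was 1.08 from 0, reached by 1 split, itself, and the highest of the other splits gave 0.566. Camera with the preset correlation also passed the list in 6 of the other 9 splits (lowest adjusted p = 7.60e-09, against 3.94e-21). Each of those 9 splits divides the groups unevenly, so it keeps part of the real difference and is no reference without a change.

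The higher ribosomal protein genes could come from library preparation, since these transcripts are short. With the length and GC trends removed the median was still 0.52, and without cKO_265, the library farthest from the others, it was 0.51, which argues against these as the whole source. Under quantile normalization the median was 0.18, and the cause of this was not tested. Whether Jmjd3 loss, the Cre construct or another difference in RNA amplification lies behind the pattern stays open.

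Slc13a2 is a candidate for an effect of the Foxn1-Cre construct, a hypothesis found from its place beside Foxn1. The gap of 7.93 kb prompted the hypothesis and is no test of it: a construct built from the region upstream of Foxn1, or inserted there, could act on this gene or carry copies of it. A change over the whole neighbourhood is argued against by the other 48 genes within 1000 kb, whose median was -0.12. Their range was from -0.57 to 1.16, so a rise of single neighbours is not excluded. The controls carried no Cre, so the construct and the loss of Jmjd3 are not separated by the design, and the labels do not say how the Cre allele was made. Mice with Foxn1-cre and intact Jmjd3 would decide between them.

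The real split gave 6 lists past camera. Of the 10 splits of the libraries, 5 gave at least as many, the real one included, and the highest other gave 13. For changed genes the real split gave 12, reached by 1 split, itself, and the highest other 0. With 10 splits a share under 0.05 cannot be reached, so neither count is judged against chance. The split with 13 set Con_253, Con_261 and cKO_265 against the rest, and what sets it apart was not tested.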
